A study of Mus musculus with 7 samples.

How the data were processed

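The series compares islets of control mice (Gata6 flox/flox, 3 arrays) with islets of mice labelled Gata6 KO (Gata6 flox/flox with Pdx1-Cre, 4 arrays), each array a pool of 3 mice aged 2 months. Islets were isolated by collagenase digestion, and biotin-labelled cDNA made from total RNA was hybridised to Affymetrix mouse gene arrays of the whole-transcript type, per the labels' protocols. The controls carry no Cre transgene, so an effect of Cre is not separated from one of Gata6.

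The log2 values were normalized and summarised with RMA by the authors before they were deposited, per the submitters' processing notes, which name RMA and Transcriptome Analysis Console without versions. Base 2 is taken from RMA, whose output is in log2 units. RMA corrects the background, normalizes quantiles and summarises the probes of a probe set, but medians over all probe sets still differed between the groups, so the deposited table is not fully quantile-normalized over them. Whether further steps were taken, and the genome build, is not given in the sources used here. Values ran from -0.59 to 13.545. A low log2 value lies near the array's background, where fold changes are compressed, and values near the top can be saturated. No scanner files or detection calls were used here.

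Probe sets were named through the platform annotation supplied with the series. Of 41345 probe sets 23521 had 1 gene symbol, 1814 had several and 16010 were unnamed here. Genes were named from probe sets with 1 symbol. Where a gene had several such probe sets (1082 genes), the one with the highest mean over all arrays was used, which left 22180 genes, 21994 of them with an identifier found in the RefSeq gene table of assembly GRCm38.p6. That table served for older and newer symbols and no coordinates were taken from it. Ins1, which the naming rule always includes, had no probe set of a single gene and is not analysed here.

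Each gene was tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend) for the difference between the groups, with no covariate, at a Benjamini-Hochberg adjusted p under 0.05 over all genes. SEs are moderated. All tests were two-sided. Exact permutation tests used the absolute difference of group means over the 35 splits of 7 arrays into 3 and 4, so that their smallest p is 0.0286. The 34 gene lists named 729 genes, 652 of them measured by a probe set of a single gene. They were written before the data were examined, as were the tests and the first set of alternatives. Lists were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 34 lists, and beside it with an estimated correlation, with fry and with exact permutation of the list mean per array. Members were counted with p adjusted over all genes and adjusted over the list alone.

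The genes named in the text follow a rule set before the data were examined: a fixed set of islet genes that includes Gata6, Ins1, Ins2, Gcg, Sst, Ppy, Pdx1, Nkx6-1, Mafa and Slc2a2, the 10 largest rises and 10 largest falls among genes past the threshold whose groups do not overlap, up to 4 members with the smallest p of each list, and the 2 most abundant members of each list of another cell type. Gene models without a name and microRNAs were left out of the largest changes. The rule covered 167 measured genes.

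The tests were tried on simulated data for this comparison, with the 22180 genes' own means and spread. Of genes with a simulated log2 change of 1, 47% were recovered, and of those with a change of 2, 92%, with a mean estimate of 2.01. Of the calls 2.11% were unchanged genes. The simulation changed far fewer genes than the 5486 called in the data, so these shares need not hold there. A shifted list was called, and 0 of the unshifted lists. The simulated genes were drawn independently, whereas the estimated correlation in the data was 0.486 for the beta-cell identity list. The simulation therefore does not measure how often lists are called falsely in these data.

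Alternatives covered centring of each array on its median, a repeated quantile normalization, leaving out the 40% of genes with the lowest mean, the mean of all probe sets of a gene, all probe sets whether named or not, eBayes without trend or with robust estimation, array quality weights, other thresholds, the replicate number as a block, the acinar list mean as a covariate and leaving out each array in turn. Added after the values were seen were a block for arrays with low and high Xist, the arrays with high Xist alone, a fit without the arrays labelled Gata6 KO 3 and 4, and a fit without small RNA and ribosomal protein genes. Figures were drawn with matplotlib 3.10.9.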

Results

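Gene expression was measured in pancreatic islets of mice on 7 whole-transcript arrays. The 3 control arrays carried RNA of mice with floxed Gata6 alleles and no Cre. The 4 arrays labelled Gata6 KO carried RNA of mice with the same floxed alleles and a Pdx1-Cre transgene, which is active in the pancreatic epithelium. Each array held islets pooled from 3 mice aged 2 months, so the replicates are separate pools of animals and the p-values cover the spread between pools. The deposited values were log2 signals of 41345 probe sets, and 22180 genes were tested. The number of arrays limits the precision. Medians over all probe sets lay between 1.72 and 1.78 on the control arrays and between 1.89 and 2.11 on the arrays labelled Gata6 KO.

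Gata6, the targeted transcription factor, was not lower on the arrays labelled Gata6 KO. Its log2 signal was 4.60, 4.80 and 4.83 on the control arrays and 5.41, 5.35, 5.34 and 5.01 on the others. The difference was 0.54 with an SE of 0.20, which did not pass limma's test (Benjamini-Hochberg adjusted p = 0.0622) or the exact two-sided permutation test (p = 0.0571, smallest possible p = 0.0286). The sources used here give neither the floxed exons nor the position of the probes, so a probe set outside the deleted part would check nothing. None of the 8 measured GATA factors and their FOG cofactors passed the test, also when adjusted over the list alone. At an unadjusted p under 0.05, Gata1, Gata4 and Gata6 differed, each towards higher values. Part of this is the median difference of all genes, 0.17. Minus that shift they changed by 0.26 (SE 0.19), 0.39 (SE 0.23) and 0.37 (SE 0.20). Gata4 measured 4.80 ± 0.31 (SD, n = 3) on the control arrays and 5.35 ± 0.28 (SD, n = 4) on the others. Directions below are those of the labels, which the Gata6 signal went against.

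The comparison of the labelled genotypes asks how islet expression differs when Gata6 is targeted. On the arrays labelled Gata6 KO, 21 of 25 beta-cell, 7 of 10 alpha-cell and 6 of 11 delta, PP and epsilon cell genes were lower. In each of these lists 1 gene was higher. The lists passed camera's test with a preset correlation but not with an estimated one (adjusted p = 0.270, adjusted p = 0.106 and adjusted p = 0.283). The pancreatic polypeptide gene Ppy measured 11.53 ± 0.20 (SD, n = 3) on the control arrays and 6.97 ± 1.88 (SD, n = 4) on the arrays labelled Gata6 KO, the largest fall among the named genes. Of the markers of other cell types, 20 of 33 acinar, 12 of 22 mesenchymal and 8 of 19 lymphoid genes were higher, as were several small nucleolar RNA (snoRNA) genes. These 3 lists passed the test with a preset correlation (adjusted p = 0.284, adjusted p = 0.655 and adjusted p = 0.300 with an estimated correlation). The largest rise among the named genes was that of the snoRNA gene Snora34, from 2.30 ± 0.67 (SD, n = 3) to 7.51 ± 0.66 (SD, n = 4). Without the array labelled Gata6 KO 4 the log2 difference of Snora31 (6.21) was larger than that of Snora34 (5.54).

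Between the groups 5486 genes changed at an adjusted p under 0.05 (limma, Benjamini-Hochberg), 3853 higher and 1633 lower, and 2362 of them changed at least 2-fold. The groups did not overlap for 34.3% of the genes, against 5.71% by chance. The split by direction depended on the scaling. The median log2 difference of all genes was 0.17, and 70.2% of the changed genes were higher, against 40.3% after centring each array on its median and 41.1% after a repeated quantile normalization. Changes are therefore given below as log2 differences minus this shift, with the SE and p of the unshifted difference. A total of 3265 genes passed without control array 1 and 3586 without control array 2, and 3337 on the 5 arrays with high Xist, a choice made after the values were seen. With the acinar list mean as a covariate 18 genes passed, and the group accounted for 96.1% of the variance of that mean. The labels name no array or preparation batch, so none could be tested.

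Beta-cell identity genes fell as a group on the arrays labelled Gata6 KO. Of 25 measured members 21 fell and 1 rose, and 23 fell and 1 rose when adjusted over the list alone. Their median change was -1.65 relative to all genes (camera adjusted p = 1.49e-19; adjusted p = 0.270 with an estimated correlation). Rfx6, a transcription factor of endocrine development, changed by -2.84 (SE 0.22, adjusted p = 3.25e-06). Glp1r, the receptor of the incretin GLP-1, changed by -2.74 (SE 0.24) and Pax6 by -2.51 (SE 0.22). The beta-cell transcription factors Nkx6-1, Pdx1 and Mafa changed by -2.58 (SE 0.26), -1.65 (SE 0.22) and -1.15 (SE 0.21). Slc2a2, the glucose transporter GLUT2, changed by -3.44 (SE 0.53). Without the array labelled Gata6 KO 3 its unshifted difference went from -3.27 to -2.59. The insulin gene Ins2 changed by -1.66 (SE 0.35, adjusted p = 0.0074). This call was lost without control array 1 (adjusted p = 0.0541), and the adjusted p ranged from 9.17e-04 to 0.891 over all alternatives, the acinar covariate included. Ins2 measured 9.18 ± 0.64 (SD, n = 3) on the control arrays, below Gcg (11.98 ± 0.15) and Sst (12.20 ± 0.18). How the Ins2 probe set responds was not checked here, so this level is uncertain. The mean of the acinar list was 10.07 ± 0.09 (SD, n = 3) on the control arrays and 10.88 ± 0.10 (SD, n = 4) on the others, and it moved opposite to this and the following endocrine groups.

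**Figure D1:**
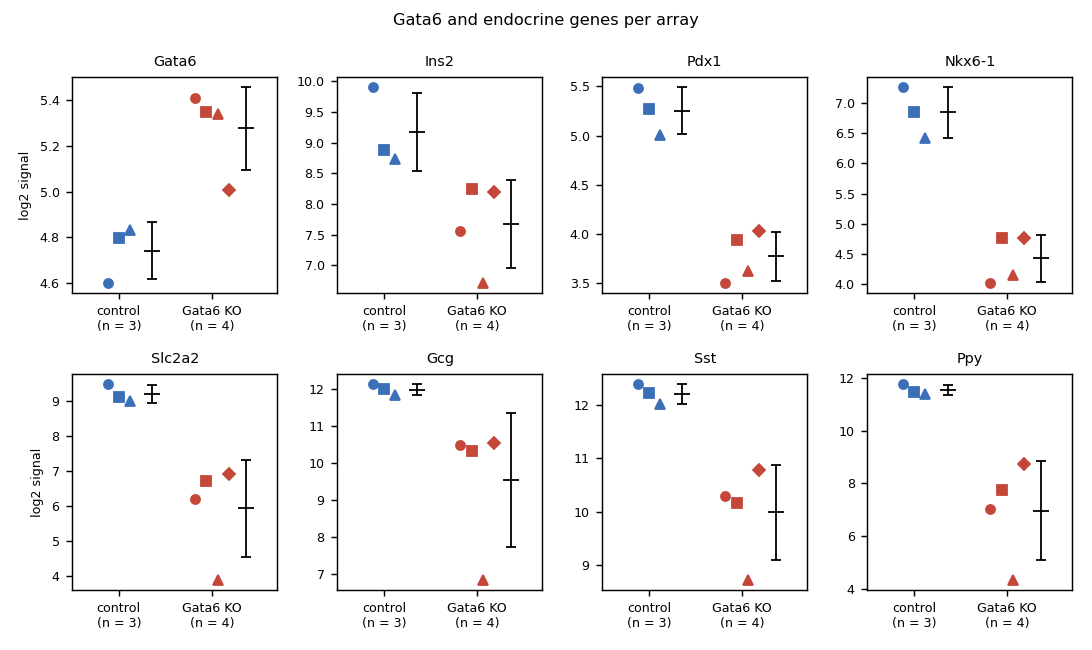
Log2 signal of Gata6 and 7 endocrine genes on each array (points; a marker shape stands for a replicate number), with the mean and SD of each group beside them; vertical axes differ between panels and do not start at 0. Gata6 lay between 4.60 and 4.83 on the control arrays and between 5.01 and 5.41 on the arrays labelled Gata6 KO, while Ppy averaged 11.53 and 6.97.

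Secretory granule and exocytosis genes showed the lowest median of the lists. Of 29 measured members 23 fell and 1 rose, with the same counts when adjusted over the list alone. The median change was -2.21 (camera adjusted p = 2.71e-19; adjusted p = 0.246 with an estimated correlation). Snap25, a SNARE protein of exocytosis, changed by -4.14 (SE 0.34, adjusted p = 4.84e-06). Pcsk1n, an inhibitor of the prohormone convertase PC1, changed by -3.81 (SE 0.24), and the granule protein gene Chgb by -3.91 (SE 0.49). The calcium sensor Syt4 and the priming factor Cadps changed by -3.35 (SE 0.31) and -2.98 (SE 0.30). Of 20 measured ion channel genes of stimulus-secretion coupling, 15 fell and 1 rose, and 16 fell and 1 rose when adjusted over the list alone. Their median change was -1.49 (camera adjusted p = 1.28e-13; adjusted p = 0.106 with an estimated correlation). Abcc8, the sulfonylurea receptor subunit of the KATP channel, changed by -3.47 (SE 0.32), the calcium pump Atp2a3 by -2.82 (SE 0.28) and the calcium channel Cacna1d by -2.44 (SE 0.22).

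The other hormone cell types moved the same way. Of 10 measured alpha-cell genes 7 fell and 1 rose, and 8 fell and 1 rose when adjusted over the list alone. Their median change was -1.30 (camera adjusted p = 8.23e-06; adjusted p = 0.106 with an estimated correlation). Ttr, which encodes transthyretin, changed by -2.35 (SE 0.23) and the transcription factor Irx2 by -1.43 (SE 0.20). The glucagon gene Gcg changed by -2.59 (SE 0.66, adjusted p = 0.0157). That call was lost without control array 1 (adjusted p = 0.0615) and without control array 2 (adjusted p = 0.0538). The Gcg adjusted p ranged from 6.58e-05 to 0.8288 over all alternatives, the acinar covariate included. Its size rests in part on the array labelled Gata6 KO 3, without which the unshifted Gcg difference went from -2.42 to -1.52. Of 11 measured delta, PP and epsilon cell genes 6 fell and 1 rose, also when adjusted over the list alone. The median change was -1.23 (camera adjusted p = 4.03e-05; adjusted p = 0.283 with an estimated correlation). Ppy, peptide YY (Pyy) and somatostatin (Sst) changed by -4.73 (SE 0.69), -3.42 (SE 0.46) and -2.38 (SE 0.35). Without the array labelled Gata6 KO 3 the unshifted Ppy difference went from -4.56 to -3.69.

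Genes held low in mature beta cells, the beta-cell disallowed list, rose. Of 24 measured members 16 rose and 0 fell, and 18 rose when adjusted over the list alone. Their median change was 0.65 (camera adjusted p = 9.18e-06; adjusted p = 0.349 with an estimated correlation), and the list holds 4 genes that other lists also hold. The growth factor binding protein gene Igfbp4 changed by 1.55 (SE 0.27) and the LIM protein gene Lmo4 by 1.11 (SE 0.19). These genes are expressed in many other cell types, and the acinar list mean was higher on the same arrays. Of 17 progenitor and dedifferentiation genes 5 rose and 2 fell, also when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.480).

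Markers of other pancreatic cells were compared because collagenase-isolated islets can carry them. Of 33 measured acinar genes 20 rose and 0 fell, and 22 rose and 1 fell when adjusted over the list alone. Their median change was 0.50 (camera adjusted p = 1.15e-06; adjusted p = 0.284 with an estimated correlation). The secretory trypsin inhibitor Spink1 changed by 1.74 (SE 0.18). The amylase gene Amy2b and the trypsinogen gene Prss2 changed by 2.66 (SE 0.24) and 1.57 (SE 0.18), and both have near-identical paralogs that probes may share. The most abundant acinar genes, Ctrb1 and Cela1, measured 13.40 ± 0.03 and 13.22 ± 0.07 (SD, n = 3) on the control arrays. They measured 13.45 ± 0.07 and 13.24 ± 0.09 (SD, n = 4) on the others. Ctrb1 itself gave the highest value on each control array and the highest on any array, 13.545 on the array labelled Gata6 KO 4. Values this close to the top can be saturated. Of 22 mesenchymal genes 12 rose and 0 fell, also when adjusted over the list alone, with a median of 0.80 (camera adjusted p = 0.00587; adjusted p = 0.655 with an estimated correlation). The collagen genes Col3a1 and Col6a2 changed by 1.90 (SE 0.44) and 1.44 (SE 0.26).

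Of 19 lymphoid genes 8 rose and 0 fell, and 13 rose when adjusted over the list alone, with a median of 0.62 (camera adjusted p = 2.67e-04; adjusted p = 0.300 with an estimated correlation). The lymphotoxin gene Ltb changed by 1.48 (SE 0.24) and the T-cell gene Cd5 by 1.23 (SE 0.21). Their signals were low, with means of 2.26 and 1.64 on the control arrays, where the lymphoid list mean was 2.16 ± 0.12 (SD, n = 3). Of 21 myeloid genes 7 rose and 0 fell, also when adjusted over the list alone (median 0.34, camera adjusted p = 0.0345; adjusted p = 0.663 with an estimated correlation). The myeloid call was lost without the array labelled Gata6 KO 1 (adjusted p = 0.357) and without control array 2 (adjusted p = 0.0908), in a range from 1.45e-05 to 0.663. Of 20 endothelial genes 5 fell and 2 rose, and 5 fell and 3 rose when adjusted over the list alone (median -0.38, camera adjusted p = 0.0255; adjusted p = 0.597 with an estimated correlation). Esm1, which marks endothelial tip cells, and the VEGF receptors Flt1 and Kdr changed by -2.39 (SE 0.26), -1.73 (SE 0.26) and -1.47 (SE 0.23), while Egfl7 changed by 1.01 (SE 0.21). The endothelial call was lost without control array 3 (adjusted p = 0.0665) or the array labelled Gata6 KO 4 (adjusted p = 0.159), and after centring (adjusted p = 0.0828), in a range from 0.00421 to 0.934. With the acinar covariate its unshifted mean change turned to 0.0435.

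The ductal (5 rose and 2 fell of 18), adipocyte (4 rose of 13), glial and neuronal (2 rose and 2 fell of 11) and red blood cell lists (0 of 2) did not pass camera's test, with adjusted p from 0.480 to 0.531 and the same counts when adjusted over the list alone. In the exact permutation test of list means per array, adjusted over the 9 lists of other cell types, the smallest adjusted p was 0.0857, for the acinar, adipocyte and lymphoid lists. The median and the mean of the adipocyte list, relative to all genes, were -0.06 and 0.32.

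**Figure D2:**
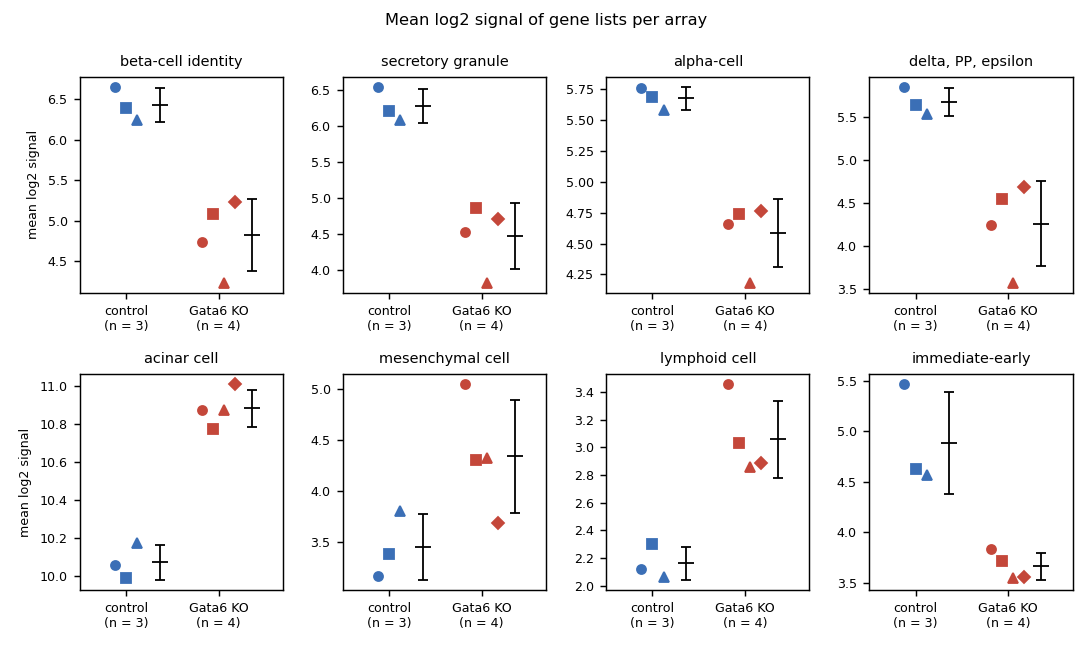
Mean log2 signal of 8 gene lists on each array (points; a marker shape stands for a replicate number), with the mean and SD of each group beside them; vertical axes differ between panels and do not start at 0. The means of the endocrine lists and of the immediate-early list were lower on each array labelled Gata6 KO than on each control array, and those of the acinar and lymphoid lists were higher.

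Immediate-early genes, which tissue dissociation can induce, were lower on the arrays labelled Gata6 KO. Of 19 measured members 11 fell and 2 rose, and 15 fell and 2 rose when adjusted over the list alone. The median change was -1.39 (camera adjusted p = 1.39e-09; adjusted p = 0.283 with an estimated correlation). The transcription factors Egr1 and Fos changed by -3.86 (SE 0.29) and -3.65 (SE 0.27), and the mRNA decay factor Zfp36 by -2.89 (SE 0.30). Of 22 inflammatory mediator genes 8 rose and 1 fell, and 12 rose and 1 fell when adjusted over the list alone (median 0.41, camera adjusted p = 0.0255; adjusted p = 0.283 with an estimated correlation). The adhesion molecule Vcam1 changed by 2.29 (SE 0.23), and the interleukin-1 receptor Il1r1 by -2.90 (SE 0.43). Of 31 proliferation genes 13 rose and 2 fell, and 16 rose and 3 fell when adjusted over the list alone (median 0.37, camera adjusted p = 0.0111; adjusted p = 0.587 with an estimated correlation). Foxm1, a transcription factor of mitotic genes, changed by 1.16 (SE 0.21) and the S-phase cyclin gene Ccna2 by 1.17 (SE 0.23). Their signals were low, with means of 1.57 and 1.44 on the control arrays. The proliferation list did not pass when the 40% of genes with the lowest means were left out (adjusted p = 0.0983, in a range from 1.20e-04 to 0.587). Of 19 STAT5 and prolactin response genes 6 fell and 2 rose, and 6 fell and 3 rose when adjusted over the list alone (median -0.36, camera adjusted p = 0.0345; adjusted p = 0.464 with an estimated correlation). The growth factor gene Wnt4 changed by -2.61 (SE 0.27), and Socs2, an inhibitor of growth hormone signalling, by 1.99 (SE 0.33). The STAT5 call was lost without control array 1 (adjusted p = 0.154) and after centring (adjusted p = 0.0828), in a range from 0.0178 to 0.823, and with the acinar covariate its unshifted mean change turned to 0.15. The acinar and lymphoid list means were higher on each array labelled Gata6 KO than on each control array, while the mesenchymal mean of array 4 (3.69) lay below that of control array 3 (3.80).

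The metabolic, ER stress, interferon, p53, antioxidant and autophagy lists did not pass camera's test. The respiratory chain came closest, with 11 of 32 genes higher and 3 lower, or 14 and 3 when adjusted over the list alone (adjusted p = 0.0539). It passed without control array 2 (adjusted p = 0.0351), without the array labelled Gata6 KO 3 (adjusted p = 0.0148) and after centring (adjusted p = 0.0426), in a range from 0.00746 to 0.655. Its members cytochrome c (Cycs) and Cox5a changed by 2.15 (SE 0.22) and 2.00 (SE 0.22). The interferon response list had 7 of 20 genes higher and 1 lower, or 10 and 1 over the list alone (adjusted p = 0.108). For ER stress and the unfolded protein response 7 of 32 genes rose and 4 fell, or 8 and 4 over the list alone (adjusted p = 0.936). The counts were 6 higher of 21 for the TCA cycle, 6 higher and 3 lower of 21 for glycolysis and hypoxia, 4 higher and 2 lower of 20 for fatty acid oxidation, 3 higher and 4 lower of 18 for fatty acid synthesis and 1 higher and 3 lower of 15 for cholesterol synthesis. They were 5 higher of 19 for p53 and apoptosis, 5 higher and 2 lower of 20 for antioxidant genes, 5 higher and 1 lower of 17 for autophagy and lysosome genes and 1 higher of 19 for mitochondrial biogenesis. Adjusted over the list alone, the counts of higher and lower genes became 7 and 4 for glycolysis, 7 and 2 for fatty acid oxidation, 2 and 4 for cholesterol synthesis, 6 and 1 for autophagy and 0 and 0 for mitochondrial biogenesis, and stayed the same for the other 4 of these lists. The camera adjusted p of these 9 lists lay between 0.186 and 0.936. Sod1, a superoxide dismutase, changed by 3.03 (SE 0.22), and the lipogenic transcription factor Mlxipl by -2.23 (SE 0.19). None of the 4 sex-linked genes passed.

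Of the 34 lists 15 passed camera's test, 7 higher and 8 lower. With an estimated correlation 0 passed, against 5 at an unadjusted p under 0.05, and fry's test of a shift in 1 direction called 19. Relative to all genes, median, mean and camera's direction differed in sign for the mitochondrial biogenesis, TCA cycle, adipocyte and sex-linked lists, none of which passed. The unshifted medians of the ER stress, glycolysis, fatty acid synthesis and glial lists were above 0 where camera ranked them lower.

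**Figure D3:**
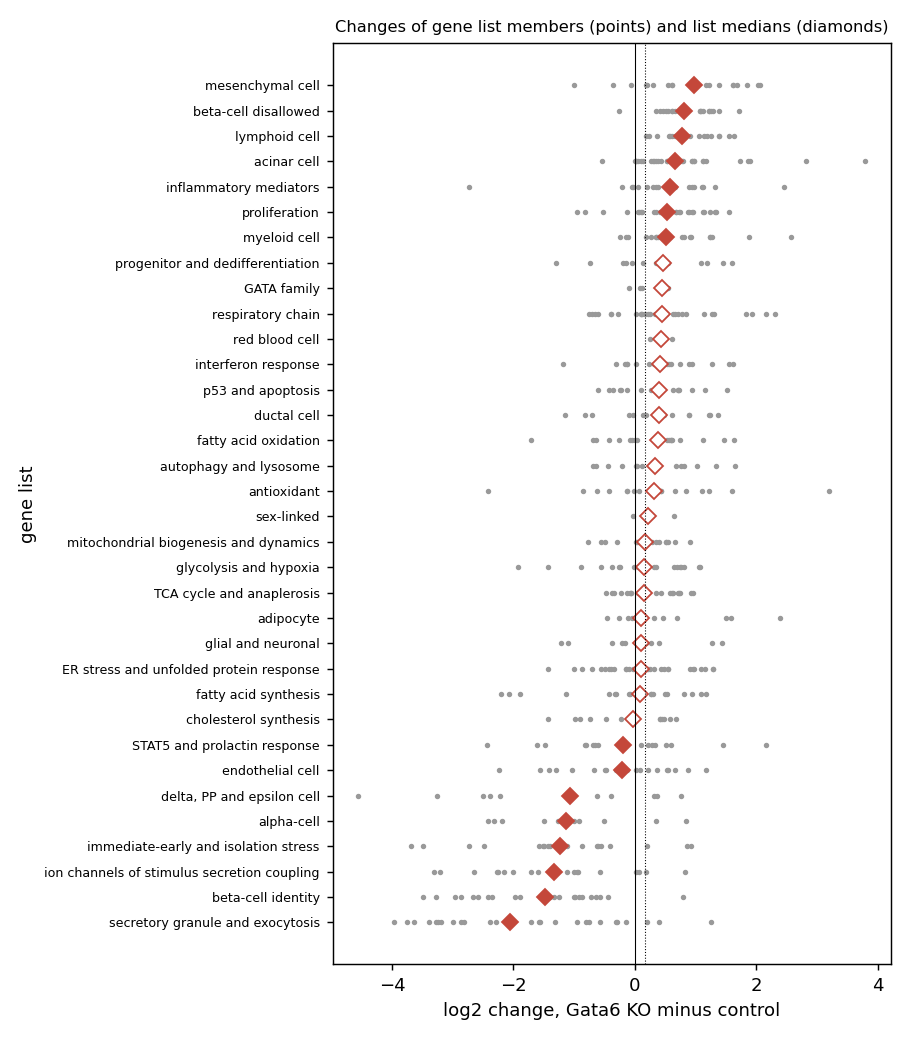
Log2 difference (arrays labelled Gata6 KO minus control) of each measured member of the 34 lists (grey points) with the list median (diamonds, filled where camera's adjusted p was under 0.05 with the preset correlation); the dotted line is the median of all genes, 0.17. Unshifted medians ran from -2.05 for secretory granule and exocytosis genes to 0.97 for mesenchymal genes.

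The 10 largest rises by the naming rule were mostly small or ribosomal transcripts. The snoRNA genes Snora34, Snora31, Snora23, Snord1b and Snora41 changed by 5.05 (SE 0.35), 4.95 (SE 0.80), 4.56 (SE 0.51), 4.32 (SE 0.32) and 4.17 (SE 0.54). The Y RNA gene Rny1 changed by 4.03 (SE 0.27), and the ribosomal protein genes Rpl9 and Rps13 by 4.98 (SE 0.27) and 4.03 (SE 0.33). Rabggtb, a subunit of Rab geranylgeranyl transferase, changed by 4.59 (SE 0.78) and Reg3a, a secreted lectin, by 4.21 (SE 0.66). Reg3a measured 5.27, 1.63 and 5.22 on the control arrays, and its unshifted difference was 3.17 to 4.99 without each array in turn. Near-identical copies of the ribosomal, snoRNA and Reg genes may share probes, so their single-gene values are uncertain. So is that of Rabggtb, which measured 6.68, 7.24, 6.16 and 2.48 on the arrays labelled Gata6 KO where Snora31 measured 7.30, 7.55, 7.04 and 2.92, and the sharing of probes with snoRNAs was not checked here. Besides Ppy, Snap25, Chgb, Pcsk1n and Egr1, the 10 largest falls held Gpr158, Papss2, Fbxl16, Peg3 and Pde5a, with changes of -3.85 (SE 0.45), -3.82 (SE 0.46), -3.71 (SE 0.34), -3.70 (SE 0.58) and -3.68 (SE 0.37).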

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

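The tests of a change confined to beta cells, of a lower share of islet RNA, of fewer endocrine cells and of exchanged arrays were chosen only after the result was seen, as was the choice of small RNA classes. Directions are those of the labels, which the Gata6 signal went against, and differences in this part are not adjusted for the median shift unless given as relative to all genes.

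In the group of 4 arrays, 201 values of named genes and list means were searched for an array far from the other 3, and 18 were found, where chance gives about 5%. The arrays labelled Gata6 KO 3 and 4 held 7 each, array 1 held 3 and array 2 held 1. Array 3 stood low for the glucagon gene Gcg (6.85, others 10.3 to 10.6), the imprinted zinc finger gene Peg3 (3.15, others 6.03 to 6.32) and the mean of the glycolysis and hypoxia list (4.26, others 4.52 to 4.57). It stood high for the hexokinase gene Hk2 (3.68, others 3.33 to 3.36) and the sodium channel gene Scn9a (2.11, others 1.65 to 1.71). It was also low for the X-inactivation RNA Xist (2.15, others 5.16 to 5.60) and high for the Y-linked Kdm5d (1.88, others 0.897 to 1.01).

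Array 4 of the same group stood low for the snoRNA genes Snora31 (2.92, others 7.04 to 7.55) and Snora41 (5.30, others 8.05 to 8.30) and for Gata6 (5.01, others 5.34 to 5.41). It stood low for the fatty acid binding protein gene Fabp4 (2.43, others 5.80 to 6.47), cytochrome c Cycs (6.67, others 7.11 to 7.20) and the adhesion molecule Vcam1 (4.01, others 4.57 to 4.61), and high for the mean of the GATA family list (3.47, others 3.26 to 3.28). Array 1 stood high for the macrophage gene Aif1 (3.43, others 2.93 to 2.95) and the calcium channel gene Cacna1d (2.62, others 1.99 to 2.07) and low for the VEGF receptor Flt1 (3.11, others 3.56 to 3.62). Array 2 stood high for the phosphodiesterase gene Pde5a (4.24, others 2.68 to 2.75). Outside the genes tested, 2380 of 17824 probe sets without a single gene name changed between the groups.

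Of the 35 splits of the 7 arrays, 1 gave as many changed genes as the real split, the real split itself, with 5486 genes against at most 724 in another. This argues against chance for the gene count but does not exclude it, as the smallest possible p of 35 splits is 0.0286. The other splits with 724 genes and with 15 lists each joined the control arrays with 1 array labelled Gata6 KO, so they kept part of the real contrast. For the number of lists, 2 of the 35 splits gave as many, with 15 lists for the real split and 15 for the highest other, so chance cannot be excluded for that number.

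Most measured genes of the alpha-cell, beta-cell and delta, PP and epsilon lists were lower on the arrays labelled Gata6 KO, and 1 of each list was higher. With an estimated correlation none of these lists was called. A change confined to beta cells is argued against by the glucagon, somatostatin, Ppy and Pyy genes, whose mean difference was -3.11 (exact permutation p = 0.0286, the smallest possible). A lower share of islet RNA may contribute, but alone it would lower islet genes alike, and the 20 measured members of the beta, alpha and delta lists with a mean of at least 5 over the 7 arrays, a limit that leaves out some members that fell, had differences from -4.56 to 0.84, with an SD of 1.35 against a median SE of 0.32. How far unequal probe response or expression in other cells accounts for this spread is not known, so that share stays open, as does a loss of endocrine cells, since the acinar and endothelial medians lay 0.88 apart while the endothelial members went both ways with an SD of 0.89. An effect of the genotype on endocrine cells stays open as well, and so does an unlabelled preparation batch, which cannot be told apart from the groups.

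The snoRNA genes were higher, with a median change of 1.89 relative to all genes. More transcription was looked for in 15 noncoding snoRNA host genes, which rose less than the snoRNAs. Their median change was 0.25 (95% interval over genes 0.08 to 0.65), against 2.06 for the snoRNAs on the same scale. The host genes had a mean signal of 2.70 ± 0.09 (SD, n = 3) on the control arrays and 3.16 ± 0.12 (SD, n = 4) on the others. At such low levels changes can be compressed, so more transcription of these hosts stays open, and protein-coding hosts were not tested. Different recovery or labelling of short RNA could raise snoRNAs. The other small RNA genes, microRNAs included, had a median of 0.33 relative to all genes (95% interval over genes 0.22 to 0.51). They were limited to a mean of at least 2 over all arrays, a limit not set for the snoRNAs. High values on the arrays labelled Gata6 KO can carry a gene past it, which can raise this median. The 483 microRNA genes without that limit had a median of -0.0022 relative to all genes. The median of 0.33 lay below the snoRNA median but above 0, so a part in the rise is not excluded. An effect of the genotype or of the cell types present stays open and was not tested.

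Gata6 was not lower on the arrays labelled Gata6 KO. More exocrine RNA may hide a loss only if exocrine cells kept Gata6. Pdx1-Cre is active in the pancreatic epithelium, so those cells may carry the deletion too, which was not measured. With the acinar list mean in the fit the Gata6 coefficient was 1.20 (approximate interval from its SE, -0.83 to 3.24). Its SE went from 0.20 to 1.02 because the group accounts for 96.1% of that mean. More exocrine RNA as an explanation cannot be told apart from the groups. An exchange of single arrays is argued against by the 7 arrays that each lay closer to their own group, while an exchange of all labels stays open. A probe set outside the deleted exons stays open too, as the sources used here give neither position.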

How the results depend on the processing

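The sex block, the arrays with high Xist alone, the fit without the arrays labelled Gata6 KO 3 and 4 and the fit without small RNA and ribosomal protein genes were chosen after seeing the data. Log2 differences in this part are not adjusted for the median shift, and directions are those of the labels, which Gata6 went against. Of 146 changed genes among the 167 named, 131 kept their call without any single array and 3 under every alternative that gave them a value, which leaves out the fit without small RNA genes. In the fit with the acinar covariate alone, 120 named genes lost their call with the same sign and 23 changed sign. Centring the arrays gave 1870 higher and 2769 lower genes (3503 shared calls) and a repeated quantile normalization 2018 higher and 2892 lower (3651 shared calls), since both remove most of the shift. Without each array in turn, 3265 to 5613 genes changed, 2246 to 3812 higher and 1019 to 1801 lower, lowest without control array 1 (3265) and next without control array 2 (3586), with fewer arrays in the fit. The arrays with high Xist alone gave 3337, 2231 of them higher. Gata6 passed as higher with the dimmest genes left out (0.54, adjusted p = 0.0495), without the trend (0.54, adjusted p = 0.0471), with array weights (0.57, adjusted p = 0.0312), with the replicate block (0.62, adjusted p = 0.0388), without the arrays labelled Gata6 KO 3 and 4 (0.64, adjusted p = 0.0457) and without array 4 of that group (adjusted p = 0.0333), in a range from 0.0312 to 0.775. Its difference without each array in turn was 0.46 to 0.62. The cause was not tested. With the acinar covariate, which nearly coincides with the group, 18 genes changed, 18 higher and 0 lower, and 7 lists were called. There the alpha-cell (-1.05), delta, PP and epsilon (-1.70), beta-cell disallowed (0.72), inflammatory (0.53) and immediate-early (-0.54, from -1.22) lists were no longer called, and the STAT5 (0.15) and endothelial (0.0435) lists reversed. A reversal here is a change of sign of a result that passed in the main fit, whether or not the new value passed. As 0 lower genes passed in this fit, the negative values below did not pass. Reversed genes there were Acacb -0.35, Acly 0.10, Adipoq -0.44, Car3 -0.56, Ccl2 -0.89, Edem1 -0.16, Elavl4 0.79, Gpx3 0.76, Msmo1 1.34, Muc1 -1.79, Ngfr -0.48, Pdk4 -0.31, Perp -0.0608, Plvap 1.04, Pmaip1 -0.68, Psmb8 -0.0938, Rest -0.75, Rsad2 -0.16, Sqle 0.98, Tfb1m -0.55, Tm4sf4 1.40, Try5 -0.35 and Yap1 -0.19. With an estimated correlation 0 lists were called, and the mean changes of the beta-cell (-1.61), secretory granule (-1.80), ion channel (-1.36), alpha-cell (-1.09), delta, PP and epsilon (-1.41) and acinar (0.81) lists no longer passed. The estimated correlations of these lists, from 0.026 (alpha-cell) to 0.486 (beta-cell), were above the preset 0.01. The inflammatory list, estimated at 0.0055, was lost too (adjusted p from 0.0255 to 0.283). That estimate lies below the preset correlation, so a higher correlation does not account for this loss. How far it accounts for the other losses was not settled. Other lost list calls were those of the proliferation, endothelial and myeloid lists with the dimmest genes left out, the endothelial list with the replicate block and on the arrays with high Xist alone, the endothelial and STAT5 lists after centring and without the arrays labelled Gata6 KO 3 and 4, the STAT5 list after a repeated quantile normalization and the myeloid list with the sex block. By fry the STAT5, endothelial, mesenchymal and myeloid lists were not called, and the GATA family, progenitor, respiratory chain, p53, antioxidant, autophagy, interferon and adipocyte lists were. The respiratory chain list was also gained after centring, without control array 2, without the array labelled Gata6 KO 3, on the arrays with high Xist alone and without the arrays labelled Gata6 KO 3 and 4, where the interferon list was gained too. The causes were not tested. Signal over background was not measured here, so the array level below which a change cannot be seen is not known.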

Other observations

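The gene classes of this part were chosen after their values were seen. Changes are relative to all genes, and directions are those of the labels, which Gata6 went against.

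Small nucleolar RNAs guide the modification of ribosomal and other RNAs. Of 78 snoRNA genes 64 were higher and 0 lower (limma, Benjamini-Hochberg), with 61 and 0 after centring and 60 and 1 after a repeated quantile normalization. Their mean signal was 4.82 ± 0.22 (SD, n = 3) on the control arrays and 6.88 ± 0.38 (SD, n = 4) on the arrays labelled Gata6 KO. Of 67 ribosomal protein genes 38 were higher and 0 lower, with a median of 0.55, and 26 and 3 after centring and 27 and 5 after a repeated quantile normalization. The microRNA genes had 72 higher and 5 lower of 483, with 37 and 22 after centring and 38 and 14 after a repeated quantile normalization. Their unshifted median of 0.16 became -0.07 after centring and 0.02 after a repeated quantile normalization. Of the 7 Reg genes, secreted lectins of the exocrine pancreas, 6 were higher and 0 lower (5 and 0 after centring, 4 and 0 after a repeated quantile normalization), with means of 6.47 ± 0.85 (SD, n = 3) and 8.92 ± 0.16 (SD, n = 4). Of 11 kallikrein genes of the Klk1b family 4 were higher and 0 lower, also after either scaling. Near-identical copies in these families can share probes, and snoRNAs lie within other transcripts, so single-gene values are uncertain.

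Control array 3 and the array labelled Gata6 KO 3 had a low Xist signal (1.34 and 2.15, others 5.02 to 5.60) and a high signal of the Y-linked Uty (2.52 and 2.12, others 0.71 to 1.21). With this contrast as a block 5618 genes changed between the groups. The labels do not give the sex of the mice.

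Arrays with the same replicate number had residual correlations of 0.0976, 0.00432 and 0.115. Arrays with different numbers were not compared, and both arrays numbered 3 had low Xist, so whether the numbers pair the arrays is not known. The antisense gene Gata6os measured 2.20 ± 0.19 (SD, n = 3) on the control arrays and 2.43 ± 0.22 (SD, n = 4) on the others (limma, Benjamini-Hochberg adjusted p = 0.475). The first principal component held 60.3% of the variance and separated the groups.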
